A study of Homo sapiens with 6 samples.

How the data were processed

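RNA was extracted from MB157 cells in 6 samples, 3 after GSI washout and 3 after mock washout, and libraries were made with a total RNA kit and sequenced as single reads of 75 bp, per the labels' protocols. The deposited files hold raw gene counts, 1 file per library with 57209 genes each, and were used as the authors made them, with no normalisation in the files. Per the file headers, the authors counted reads with featureCounts version 1.5.1 over exons, summed by gene, with the strand setting 1, on the Ensembl release 75 annotation of GRCh37 from which ribosomal RNA and mitochondrial genes had been removed, and 0 such genes were found in the files. The submitters' processing notes name STAR version 2.5 and Subread version 1.5.1. The header names a filtered alignment as input, and the filter is not given in the sources used here. The counting command in the headers sets no option for reads that map to several places or overlap several genes, so genes with close copies, and genes that overlap on the same strand, can lose reads. Coordinates are GRCh37, as the count files give them. Gene symbols, older symbols and gene classes came from gene name tables and GENCODE release 29 by Ensembl identifier, without use of its coordinates, and 51452 identifiers (89.9%) matched a name. An identifier without a match was not named.

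Each library was grouped by its label, and the replicate numbers are those in the sample titles. Replicates of one group were compared by a chi-square test of their counts, which gave 6.71 to 24.7 per degree of freedom, so no pair was one library counted again. Genes were kept by the filterByExpr rule of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 16649. Library sizes were scaled by the trimmed mean of M-values, with factors from 0.939 to 1.08. Washout and mock washout were compared by edgeR's quasi-likelihood test with the group as the single term, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are washout minus mock washout. Their standard errors were back-calculated as the absolute log2 fold change over the square root of the test's F statistic. They therefore add no measure of precision beyond the p-values. CPM values are scaled by the same factors and given as mean ± SD over 3 libraries. Total counts ran from 14185986 to 27326929 per library. Floors for genes at 0 counts use 3 counts over the group at 0 and cover counting error in that group only. Reads without molecular identifiers are not independent molecules.

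For the 22 gene lists, camera was run on the edgeR fit with a preset correlation of 0.01 between genes, two-sided, with adjustment over all lists, and beside it camera with a correlation estimated from the data and fry. With an estimated correlation, the calls that held were those of canonical Notch targets, Notch targets in cancer, and MYC targets and ribosome biogenesis. For interferon-response genes the estimate was -0.004, below the preset of 0.01, yet their adjusted p went from 0.000152 to 0.0582. A call lost in this variant therefore does not by itself show correlation among the genes. Members past the threshold were counted over all genes and again adjusted over the list alone. The list members BOP1, UHRF1 and PECAM1 matched no identifier by name and were left out. The grouping, the test, the lists, the alternatives except those stated otherwise, and the rule for named genes were chosen before the data were examined. That rule named the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 log2 CPM, no overlap of CPM between groups and a symbol that is not a clone name, every tested member of both Notch target lists, and from each other list the 3 members with the smallest adjusted p; some genes that it names are not reported here. Gene families taken from symbols were chosen after the comparison had been seen.

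The procedure was tested on simulated counts for the same 16649 genes. Of 50 genes changed by each size, 21 were recovered at 1.3-fold, 40 at 1.5-fold, 46 at 2-fold and 50 at 4-fold, with 16 false calls, 9.25% of the calls made. The smallest simulated size was set after other small sizes had been tried. Genes to be changed were drawn only from those above a minimum mean count, so recovery of genes with lower counts was not measured. A list raised in the simulation had a camera p of 4.81e-66, and 2 of 100 unchanged lists had a p under 0.05. Genes were drawn independently and few were changed, unlike in the data. The simulation therefore does not measure the error of camera for lists of correlated genes.

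Alternatives tried were relative log expression and upper quartile scaling, no filter on low counts or at least 10 counts in every library, DESeq2 1.42.0, limma-voom with limma 3.58.1, each library left out in turn, the replicate number as a block, a trend on gene length removed with and without that block, and short non-coding RNA genes left out. Total-count scaling and removal of a trend on GC content were added after seeing the data. Computations used R 4.3.3 and Python 3.11.15.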

Results

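The transcriptome of MB157, an established triple-negative breast cancer cell line, was measured by RNA sequencing after Notch signalling had been blocked and then either released or kept blocked. Notch receptors are cleaved by gamma-secretase, which frees an intracellular fragment that enters the nucleus and activates transcription with the DNA-binding protein RBPJ. Cells were held for 72 h in 1 µM compound E, a gamma-secretase inhibitor (GSI), washed, and cultured for a further 5 h either with the solvent DMSO, termed washout, or with 1 µM GSI, termed mock washout. Each condition had 3 libraries made from 800 ng of total RNA, with RNA integrity numbers above 9.5. The mock washout libraries held 27326929, 26237847 and 18734960 gene counts in total, and the washout libraries 24256008, 18275834 and 14185986. The small nuclear RNA 7SK took 9.19%, 5.87% and 7.45% of the counts in mock washout replicates 1 to 3 and 8.91%, 9.52% and 6.52% in washout replicates 1 to 3. The labels do not say that the replicates came from separate cultures, so the p-values of single genes measure only the spread between these samples, which may be technical. Camera compares the genes of a list with other genes. With the preset correlation its p-values treat genes as nearly independent. They do not measure how the shift of a list varies between samples.

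The design holds one comparison, washout against mock washout, which asks which transcripts change within 5 h of restoring gamma-secretase activity in cells that have been held without Notch signalling. Restoring it was followed by a rise of the HES and HEY repressors, of NRARP, a feedback inhibitor of Notch, and of the Notch ligand JAG1, whose mean level went from 94.6 ± 5.48 to 1030 ± 40.2 CPM (counts scaled to one common library total; mean ± SD, n = 3 per group). The growth regulators MYC and CCND1 (cyclin D1) rose 5.14-fold and 3.68-fold. Genes in a list of MYC targets and ribosome biogenesis rose together, with 35 of 39 tested members higher. Falls were found in 21 of 30 mitotic, 14 of 23 interferon-response and 11 of 23 epithelial and luminal genes. The calls of these lists were lost in the camera variant with an estimated correlation (adjusted p = 0.11, 0.0582 and 0.137). For the interferon list that estimate was not above the preset. The epithelial transcription factor ELF3 was 5.34-fold lower.

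Of 16649 genes tested, 7199 (43.2%) passed an adjusted p threshold of 0.05 in edgeR's quasi-likelihood test, 3775 of them higher and 3424 lower after washout. With a change of at least 2-fold required as well, 835 genes were higher and 314 lower. In 8974 genes, 53.9% of those tested, the 3 washout libraries did not overlap the 3 mock washout libraries, where chance gives 10%. The biological coefficient of variation between libraries of a group was 7.94%. Scaling by total counts alone, an alternative chosen after seeing the data, lowered the share of calls that were higher from 52.4% to 34.1% and moved the median log2 fold change of all genes by -0.13. With at least 10 counts required in every library, 202 genes were lower by at least 2-fold. Washout replicate 3 stood apart from washout replicates 1 and 2 on the second principal component, at -33.48 against 12.87 and 23.16, a component that held 15.3% of the variance; the first held 63.9% and separated the groups. Without that library 7328 genes were called, 3855 higher and 3473 lower.

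**Figure D1:**
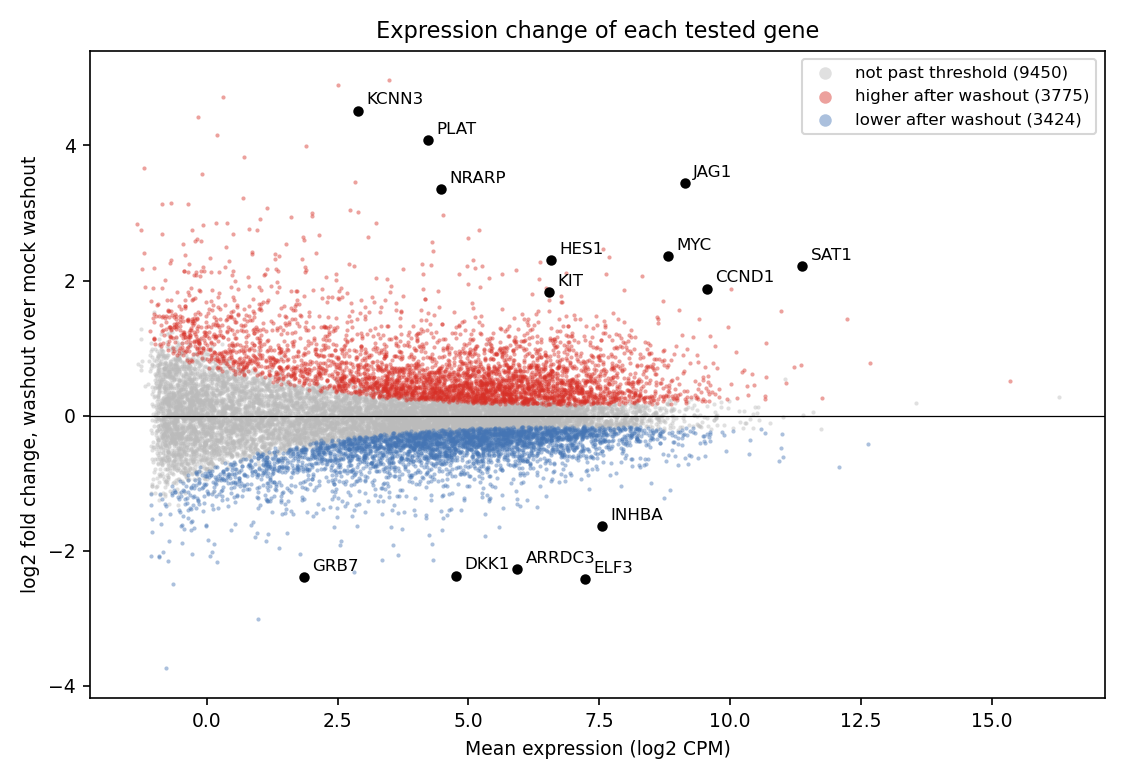
Log2 fold change of washout over mock washout against mean expression in log2 CPM for the 16649 tested genes, 1 point per gene. Red points are the 3775 genes that were higher after washout, blue points the 3424 that were lower and grey points the 9450 that did not pass the threshold; black points are genes named in the text, with JAG1 at 3.44 and ELF3 at -2.42.

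Canonical Notch target genes rose as a group. Of 9 tested members 7 rose and 0 fell, and the same counts were found when p-values were adjusted over the list alone. Their median log2 fold change was 1.47, and the list stood above other genes with an adjusted p of 2.03e-12 in edgeR's camera test, or adjusted p = 0.0177 with an estimated correlation. NRARP (chromosome 9, 140194083 to 140196703, GRCh37) had the largest rise, from 4.13 ± 0.900 to 42.1 ± 2.61 CPM, a log2 fold change of 3.35 ± 0.131 (SE). HES1 (chromosome 3, 193853934 to 193856521), a basic helix-loop-helix repressor, rose from 32.7 ± 1.28 to 161 ± 21.8 CPM, with a log2 fold change of 2.30 ± 0.093 and an adjusted p of 9.76e-09. HEY1 rose by a log2 fold change of 2.09 ± 0.257, HES2 by 1.76 ± 0.263, HEY2 by 1.47 ± 0.148, HES4 by 1.36 ± 0.104 and HEYL by 1.32 ± 0.152, the last 3 from baselines of 2.12, 12.8 and 2.40 CPM. HES5 was too sparse to test, with 0 counts in the mock washout libraries and 10, 3 and 4 counts in washout replicates 1 to 3. Set against a floor of 3 counts over the mock washout group, the observed washout counts of HES5 were 7.92-fold higher. That value allows for counting error in the mock washout group only, so it is not a lower limit. With HES5 at that value the median of the list was 1.61. The ubiquitin ligase gene DTX1 did not pass the test at a log2 fold change of 0.30 ± 0.261 (adjusted p = 0.379), and neither did NOTCH3 at -0.055 ± 0.086 (adjusted p = 0.634), whose sign turned to 0.026 without washout replicate 3. Without that library 7 canonical targets rose and 0 fell. For every gene named here and below as having risen or fallen, all 3 washout libraries lay on one side of all 3 mock washout libraries unless stated otherwise.

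Among genes known as Notch targets in cancer, 6 of 10 tested members rose and 1 fell, or 7 and 1 adjusted over the list alone. The set test gave an adjusted p of 3.53e-16, or adjusted p = 0.0177 with an estimated correlation. MYC, CCND1, SAT1 and KIT are known from work on Notch-dependent cancer lines that may include MB157, so this list is not independent evidence of its direction. MYC (chromosome 8, 128747680 to 128753674), a transcription factor that drives cell growth, rose from 147 ± 10.6 to 755 ± 90.3 CPM, a log2 fold change of 2.36 ± 0.095 (adjusted p = 9.76e-09). CCND1 (chromosome 11, 69455855 to 69469242), the cyclin that activates CDK4 and CDK6, rose from 321 ± 11.8 to 1183 ± 49.2 CPM, a log2 fold change of 1.88 ± 0.069 (adjusted p = 7.13e-09). SAT1, which acetylates spermidine and spermine, reached 4385 ± 436 CPM from 945 ± 110, a 4.64-fold rise. The receptor tyrosine kinase KIT rose 3.56-fold. RUNX1 rose by a log2 fold change of 0.28 ± 0.068 (adjusted p = 0.00591), a call that was lost with total-count scaling (adjusted p = 0.16). CCND3, which encodes cyclin D3, fell by 0.37 ± 0.113 on the log2 scale (adjusted p = 0.0186), and without mock washout replicate 2 its adjusted p was 0.0879. IGF1R, TRIB2 and BCL2 did not pass, at log2 fold changes of 0.16 ± 0.064, -0.081 ± 0.064 and 0.25 ± 0.180, with IGF1R reaching an adjusted p of 0.0407 without mock washout replicate 2 and 0.0425 with the trend on gene length removed, and TRIB2 0.0257 with total-count scaling. IL7R, LMO2 and PTCRA had too few counts to test. Without washout replicate 3, 6 of 12 tested members rose and 2 fell.

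**Figure D2:**
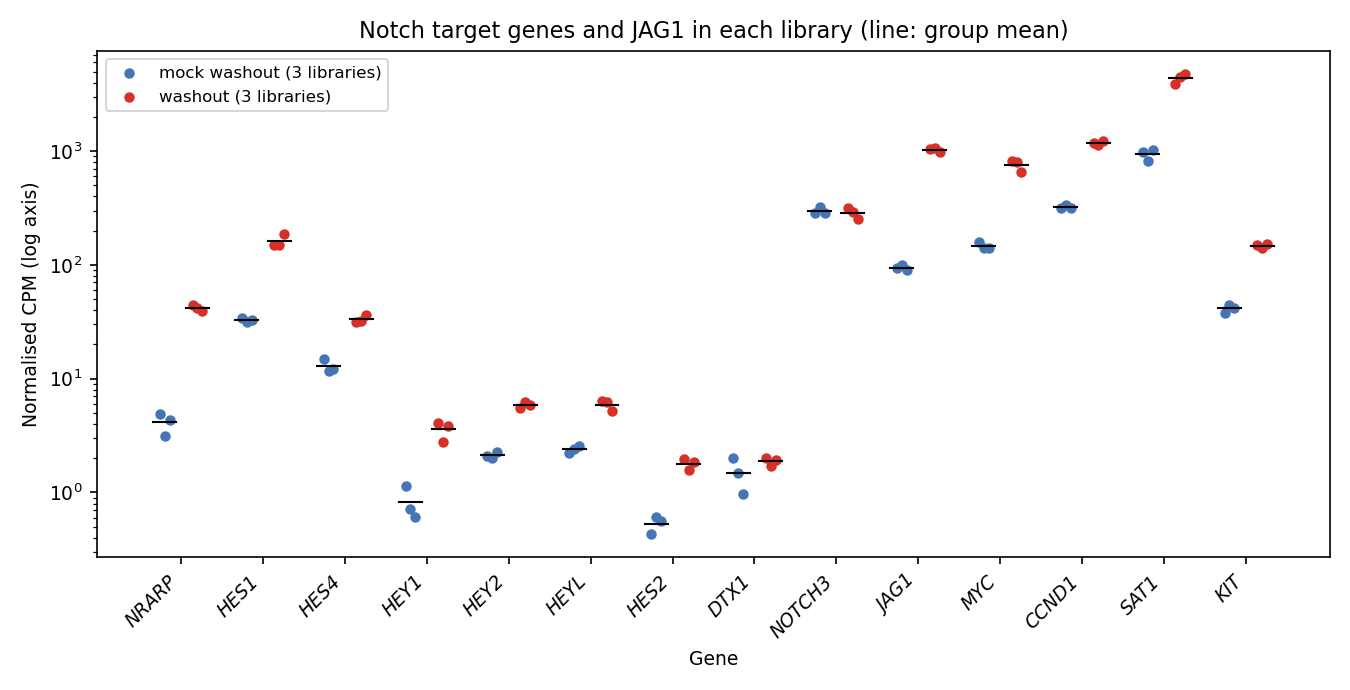
Normalised CPM on a log axis in each of the 3 mock washout libraries (blue) and 3 washout libraries (red) for canonical Notch targets, JAG1 and selected Notch targets in cancer; black lines are group means. The groups do not overlap for any gene drawn except DTX1 and NOTCH3, and the mean of MYC goes from 147 to 755 CPM.

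Among genes with a symbol that passed the test, with a mean of at least 1 log2 CPM and no overlap between groups, the largest rise was that of KCNN3 (chromosome 1, 154669931 to 154842756). This gene, which encodes a calcium-activated potassium channel, went from 0.635 ± 0.240 to 15.1 ± 1.43 CPM, a log2 fold change of 4.52 ± 0.190 (adjusted p = 1.32e-08). PLAT (chromosome 8, 42032236 to 42065242), tissue plasminogen activator, rose by 4.08 ± 0.126, and the keratin KRT6A (chromosome 12, 52880958 to 52887041) by 3.46 ± 0.170. JAG1 (chromosome 20, 10618332 to 10654694) had a log2 fold change of 3.44 ± 0.076 with the smallest adjusted p of the named genes, 1.29e-10. The antisense transcript MAP3K4-AS1, counted on its own strand, rose 8.12-fold. KCNE1, a potassium channel subunit whose annotation overlaps another gene on the same strand, rose by 2.96 ± 0.536 with a wide spread: its washout libraries held 48.3, 66.5 and 7.62 CPM against 3.80 to 6.76 CPM in the mock washout libraries. The small nucleolar and Cajal body RNAs SNORD105B, SNORD116-8 and SCARNA22 rose by log2 fold changes of 3.04 ± 0.431, 3.00 ± 0.441 and 2.95 ± 0.402. All 3 lie within other annotated genes on the same strand and belong to a class of short RNAs that rose broadly; with the trend on gene length removed their log2 fold changes were 2.13, 2.17 and 2.21, and without washout replicate 2 that of SNORD105B was 2.33.

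Falls were led by ELF3 (chromosome 1, 201977073 to 201986316), which went from 253 ± 8.93 to 47.3 ± 3.91 CPM, a log2 fold change of -2.42 ± 0.075 (adjusted p = 1.71e-09). The adaptor gene GRB7 fell by 2.39 ± 0.181 on the log2 scale, the secreted Wnt inhibitor DKK1 (chromosome 10, 54074056 to 54077802) by 2.37 ± 0.094, RNF222 by 2.31 ± 0.175 and the arrestin-domain gene ARRDC3 (chromosome 5, 90664541 to 90679176) by 2.27 ± 0.078. Smaller falls were those of FIGN (4.40-fold lower), IER5L (4.18-fold lower), ANGPTL4, a secreted inhibitor of lipoprotein lipase (3.87-fold lower), and BCL3, an atypical member of the I-kappa-B family (3.78-fold lower). RPS2P5 was 4.13-fold lower, but it is a processed pseudogene of a ribosomal protein gene whose reads can come from near-identical copies, so its value is uncertain. The same limit holds for KRT6A, KRT6B and OAZ1, which have close paralogs or pseudogenes.

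Genes known to follow MYC, most of them nucleolar, rose nearly throughout. Of 39 tested members 35 rose and 1 fell, against 35 and 2 adjusted over the list alone, with a median log2 fold change of 0.89. The list stood above other genes with an adjusted p of 1.18e-28, and adjusted p = 0.0195 with an estimated correlation. POLR3G, a subunit of RNA polymerase III, rose from 3.87 ± 0.378 to 15.8 ± 1.81 CPM, a log2 fold change of 2.03 ± 0.126. DKC1, the pseudouridine synthase of H/ACA small nucleolar particles, rose by 1.39 ± 0.080 (adjusted p = 1.73e-07), and RCL1, which acts in pre-rRNA processing, by 1.13 ± 0.070. The member that fell was LDHA, a glycolytic enzyme, by 0.37 on the log2 scale, chosen for naming after its value was seen. Without washout replicate 3 the counts were again 35 higher and 1 lower. Heat shock genes, which encode chaperones, had 9 of 14 members higher and 1 lower, with the same counts adjusted over the list alone. HSP90AB1 rose 1.68-fold, DNAJA1 1.60-fold and HSPE1, the mitochondrial co-chaperonin, 1.62-fold. The heat shock list passed at an adjusted p of 0.0349, but not with an estimated correlation (adjusted p = 0.283 with an estimated correlation), nor without mock washout replicate 2 (adjusted p = 0.0529) or with total-count scaling (adjusted p = 0.0633).

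Among cell cycle lists, that of mitotic (G2/M) genes had 0 of 30 members higher and 21 lower, the same adjusted over the list alone, and a median log2 fold change of -0.49. AURKA, a kinase of the spindle poles, fell from 52.2 ± 0.570 to 30.3 ± 1.20 CPM (log2 fold change -0.79 ± 0.066, adjusted p = 2.81e-06), HMMR fell by 0.83 ± 0.095 on the log2 scale and ANLN, which encodes anillin, by 0.58 ± 0.070. The set test gave an adjusted p of 4.76e-07, and adjusted p = 0.11 with an estimated correlation. Without washout replicate 3, 23 members were lower and 0 higher. G1/S genes went both ways, with 7 of 28 higher and 4 lower, or 8 and 5 adjusted over the list alone, and the list did not pass (adjusted p = 0.383). Their smallest p-values belonged to genes that rose: CDCA7 by a log2 fold change of 1.01 ± 0.105, CCNE1 (cyclin E1) by 0.58 ± 0.064 and CDK6 by 0.68 ± 0.079. CDK inhibitors and growth arrest genes had 4 of 20 members higher and 13 lower, the same adjusted over the list alone. CDKN1B, the inhibitor p27, fell from 26.7 ± 1.74 to 11.2 ± 1.16 CPM, and CCNG2 (cyclin G2) was 2.27-fold lower. GADD45A, a stress-induced growth arrest gene, moved the other way, from 9.73 ± 1.39 to 65.7 ± 10.4 CPM (log2 fold change 2.75 ± 0.132). The CDK inhibitor list did not pass the set test (adjusted p = 0.0568), but it passed with no filter on low counts (adjusted p = 0.00636), with limma-voom (adjusted p = 0.0221), and without mock washout replicate 3 (adjusted p = 0.0459) or washout replicate 2 (adjusted p = 0.0499).

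Notch receptors, ligands and machinery had 4 of 29 tested members higher and 11 lower, or 4 and 12 adjusted over the list alone. As a set they did not differ from other genes (adjusted p = 0.746). In edgeR's fry test of change in either direction the adjusted p was 6.34e-08. All 22 lists passed that test (largest adjusted p = 0.00289, for B cell markers), so it does not set this list apart. Besides JAG1, the nuclear protein SPEN, a co-repressor of RBPJ, rose from 321 ± 3.04 to 453 ± 14.7 CPM, and DTX2, a ubiquitin ligase of the deltex family, was 1.99-fold lower.

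Lists of signalling outputs outside Notch held more falls than rises, apart from the immediate early genes. MAPK and growth factor feedback genes had 3 of 21 members higher and 11 lower, the same adjusted over the list alone, and passed the set test at an adjusted p of 0.01, but adjusted p = 0.164 with an estimated correlation. LIF, a cytokine, was 1.89-fold lower and HBEGF, an EGF receptor ligand, 1.66-fold lower, while TGFA, another EGF receptor ligand, rose 2.76-fold. Interferon-response genes had 1 of 23 members higher and 14 lower, or 1 and 15 adjusted over the list alone, with a median log2 fold change of -0.56. IRF1 fell by 1.18 ± 0.078 on the log2 scale, RSAD2 by 1.37 ± 0.162 and RIGI, the cytosolic RNA sensor, by 0.88 ± 0.093. The member that rose was BST2, by 0.65, named after its value was seen. This list passed at an adjusted p of 0.000152, and adjusted p = 0.0582 with an estimated correlation. NF-kB and inflammatory genes had 2 of 20 members higher and 7 lower, the same adjusted over the list alone, and did not pass (adjusted p = 0.0636); it passed without washout replicate 2 (adjusted p = 0.0465) and with no filter on low counts (adjusted p = 0.0294). PTGS2, the inducible cyclooxygenase, was 2.75-fold lower, TNFAIP2 fell by 0.71 ± 0.088 and the chemokine CXCL1 rose by 0.81 ± 0.066. TGF-beta, BMP and YAP targets had 5 of 18 members higher and 10 lower, the same adjusted over the list alone, with no call for the set (adjusted p = 0.215). INHBA, the activin A subunit, fell from 283 ± 2.29 to 90.9 ± 5.60 CPM, whereas ANKRD1 and ID3 rose 4.62-fold and 4.28-fold. Immediate early genes, included because washing and medium change can induce them, had 10 of 24 members higher and 9 lower, or 11 and 9 adjusted over the list alone. Their median and mean log2 fold changes were 0.14 and 0.053 while the set test pointed down (adjusted p = 0.57). JUNB was 2.52-fold lower and ATF3 1.85-fold lower, and ARC rose 2.77-fold.

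Among metabolic and stress lists, that of hypoxia and glycolysis had 3 of 24 members higher and 15 lower, or 3 and 17 adjusted over the list alone (set test adjusted p = 0.000895, and adjusted p = 0.164 with an estimated correlation). ADM, which encodes adrenomedullin, fell by 1.65 ± 0.113 on the log2 scale and NDRG1 by 1.05 ± 0.066, while HK2, hexokinase 2, rose from 78.1 ± 3.56 to 154 ± 8.39 CPM. Polyamine genes other than SAT1 had 3 of 13 members higher and 5 lower, the same adjusted over the list alone. AMD1, the decarboxylase that feeds spermidine synthesis, rose 1.69-fold, and the antizyme genes OAZ1 and OAZ2, whose products restrain ornithine decarboxylase, were 1.85-fold and 1.36-fold lower. The polyamine median was 0.002, its mean -0.066 and its test pointed down without passing (adjusted p = 0.736). Cholesterol synthesis genes had 4 of 22 higher and 7 lower, or 4 and 8 adjusted over the list alone (adjusted p = 0.383), with SQLE at a log2 fold change of 0.38 ± 0.065 and LSS at -0.32 ± 0.073. Unfolded protein and integrated stress genes had 6 of 22 higher and 7 lower, the same adjusted over the list alone (adjusted p = 0.383). DDIT4, an inhibitor of mTORC1, was 2.77-fold lower, and the transcription factor gene XBP1 rose 1.70-fold.

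Of the markers of cell state, epithelial and luminal markers had 0 of 23 members higher and 11 lower, or 1 and 12 adjusted over the list alone. Beside ELF3, the repressor gene OVOL1 fell from 17.8 ± 0.577 to 4.77 ± 0.609 CPM and the receptor gene ERBB3 was 1.73-fold lower. The set test gave an adjusted p of 5.20e-07, and adjusted p = 0.137 with an estimated correlation. Basal and squamous markers had 6 of 20 higher and 7 lower, the same adjusted over the list alone. KRT6A, KRT6B (2.69-fold) and the desmosomal cadherin DSG3 (2.27-fold) rose. Their median was -0.084 and their mean 0.30, the test pointed up at an adjusted p of 0.045, and the call was lost with an estimated correlation (adjusted p = 0.367 with an estimated correlation), with limma-voom (adjusted p = 0.62), with upper quartile or total-count scaling (adjusted p = 0.0559 and 0.0821), with at least 10 counts required in every library (adjusted p = 0.0608), and without mock washout replicate 1, mock washout replicate 3 or washout replicate 1 (adjusted p = 0.0542, 0.0921 and 0.102). Mesenchymal markers, which also mark fibroblasts, had 4 of 17 higher and 6 lower, or 4 and 7 adjusted over the list alone, a median of -0.15, a mean of 0.081 and a test that pointed down without passing (adjusted p = 0.57). SNAI2, a repressor of epithelial genes, rose from 0.464 ± 0.0929 to 3.27 ± 0.406 CPM and TWIST2 rose 2.78-fold, while PDGFRA was 2.05-fold lower. Of 16 B cell markers 4 had enough counts to test, and 1, the complement receptor gene CR2, rose from 0.571 ± 0.254 to 2.23 ± 0.252 CPM, also when adjusted over the list alone (set test adjusted p = 0.438). Of 17 endothelial and blood vessel markers 8 were tested, with 3 higher and 3 lower, the same adjusted over the list alone. FLT1, a receptor of vascular endothelial growth factor, rose 4.30-fold and the ephrin EFNB2 1.65-fold, while SOX18 was 1.69-fold lower. The endothelial list did not pass (adjusted p = 0.0566), but it passed without washout replicate 3 (adjusted p = 0.0411), with no filter on low counts (adjusted p = 0.0294), and with a trend on gene length (adjusted p = 0.0336) or GC content (adjusted p = 0.0391) removed.

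**Figure D3:**
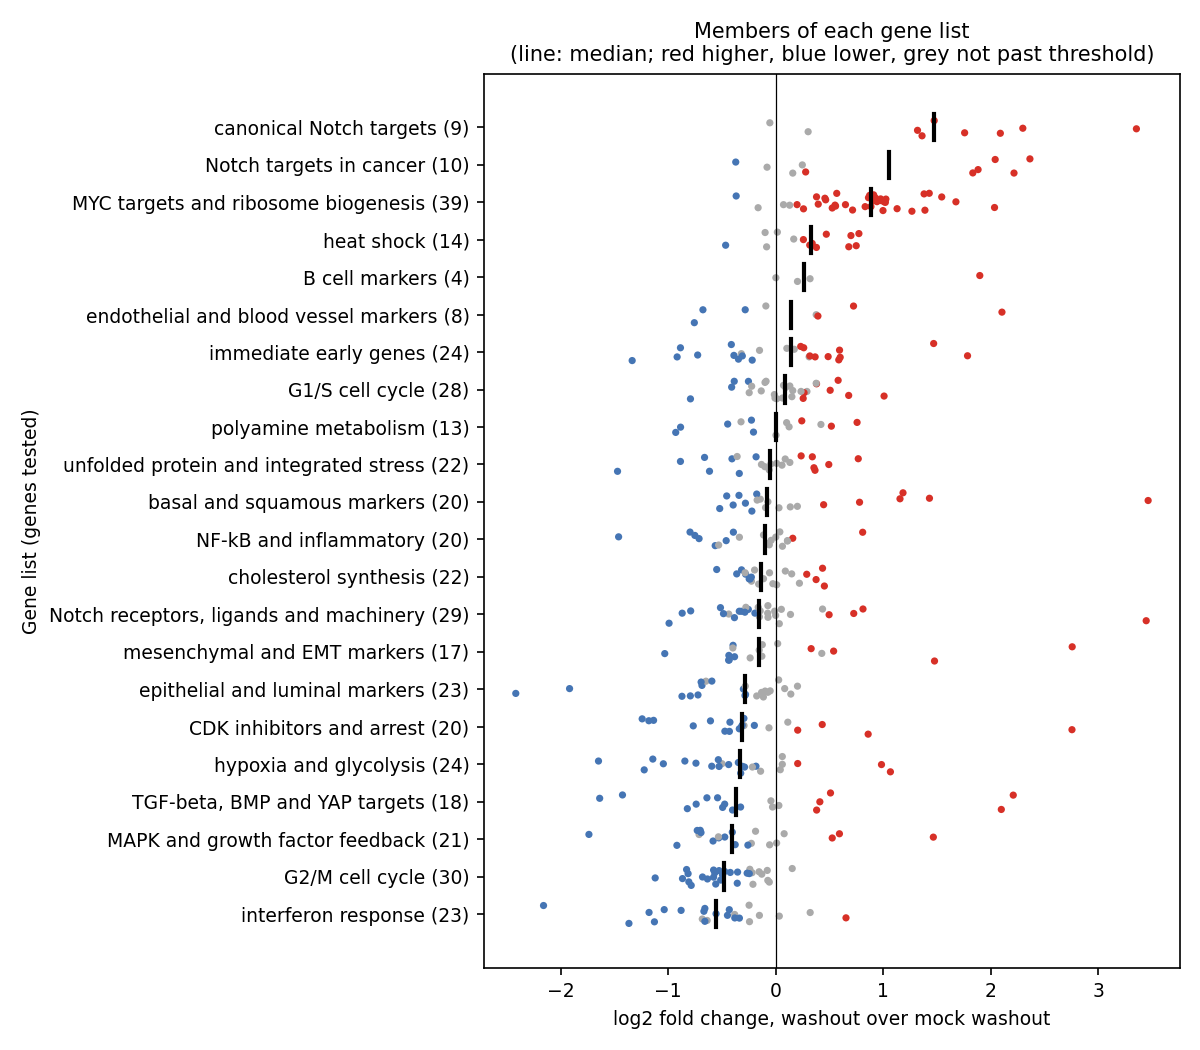
Log2 fold change of washout over mock washout for each tested member of the 22 gene lists, with the number tested in brackets and lists ordered by median (black line). Red points rose, blue points fell and grey points did not pass the threshold; medians run from -0.56 for interferon-response genes to 1.47 for canonical Notch targets.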

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

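All 4 counts of changed genes kept within 1.5 times their value under each alternative chosen before the data were examined, except the number lower by at least 2-fold, which was 202 in place of 314 when at least 10 counts were required in every library. Total-count scaling, chosen after seeing the data, gave 5227 genes lower and 504 lower by at least 2-fold, with the median of all genes moved by -0.13. It leaves out the scaling factors, which were 1.02 to 1.08 in mock washout and 0.939 to 0.97 in washout libraries. Every gene is therefore lowered by about the same amount. Why the factors differed between groups was not tested. Called genes numbered 5603 to 7328 with 1 library left out, 7196 with relative log expression scaling, 7351 with upper quartile scaling, 7225 with limma-voom and 6171 with DESeq2, and of the 6083 called by both DESeq2 and edgeR all 6083 had the same direction. With the trend on gene length removed, 6729 of 6731 genes called both ways had the same direction. Across named genes and alternatives, 1643 of 1650 values kept their direction and side of the threshold, and across gene lists 380 of 417. The NOTCH3 log2 fold change ran from -0.14 to 0.026 with 1 library left out, positive without washout replicate 3. The list of Notch receptors, ligands and machinery pointed up, far from passing, without washout replicate 3 (adjusted p = 0.874, range 0.548 to 0.874 with 1 library left out) and with the trend on gene length removed (adjusted p = 0.994, range 0.124 to 0.994 over its alternatives); the cause was not tested. The canonical Notch and MYC lists passed in all alternatives run, with adjusted p at most 0.0177 and 0.0195. Gene lists were not run with DESeq2. In fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, 7 lists passed that had not passed in camera: G1/S (adjusted p = 0.000441), B cell (0.0184) and endothelial (8.07e-05) pointing up, and CDK inhibitors (0.000953), NF-kB (0.00751), TGF-beta, BMP and YAP (0.0147) and unfolded protein (0.0408) pointing down. The replicate numbers gave no clear pairing of the samples: same-numbered libraries had correlations of -0.017, -0.023 and 0.15. Mock washout replicate 1 correlated best with washout replicate 2 (0.12), and mock washout replicate 2 with washout replicate 1 (0.10). Whether samples were paired across numbers was not tested. With the replicate number as a block, 7230 genes were called, 3794 higher and 3436 lower, and the CDK inhibitor list passed (adjusted p = 0.0488); with the trend on gene length removed as well, the endothelial list passed (adjusted p = 0.0487). In simulation at these depths and with 3 libraries per group, 21 of 50 genes changed 1.3-fold were recovered. The changed genes were all above a minimum mean count, and depth was not varied on its own.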

Other observations

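The tests in this part were planned before their results were seen, except the comparison of short RNAs matched for length, the difference between kinds of neighbouring pairs, the intervals of the ratios and total-count scaling; the gene families were chosen after the main comparison had been seen. Several families of the transcription and translation machinery stood above other genes in edgeR's camera test, though none of the families in this part passed with an estimated correlation. Of 31 subunits of RNA polymerases I, II and III, 21 rose and 1 fell, with a median log2 fold change of 0.42 and an adjusted p of 3.57e-08 in edgeR's camera test (adjusted p = 0.0801 with an estimated correlation); POLR1G rose by 1.80 ± 0.127 (SE) and POLR3K by 1.29 ± 0.125. Mitochondrial ribosomal protein genes had 35 of 74 members higher and 0 lower, among them MRPL36 at 1.54 ± 0.162 and MRPL32 at 1.10 ± 0.109 (adjusted p = 0.00129, and adjusted p = 0.4 with an estimated correlation). Non-coding host genes of small nucleolar RNAs had 15 of 25 higher and 0 lower, with SNHG1 at 1.86 ± 0.303 and SNHG8 at 1.28 ± 0.205 (adjusted p = 0.00275, and adjusted p = 0.4 with an estimated correlation). Genes with translation initiation factor symbols had 24 of 53 higher and 6 lower, with EIF5B at 1.57 ± 0.133 (adjusted p = 0.019, and adjusted p = 0.22 with an estimated correlation), and cytosolic ribosomal protein genes, whose reads can be shared with pseudogenes, 36 of 81 higher and 5 lower (adjusted p = 0.0097, and adjusted p = 0.48 with an estimated correlation). Aminoacyl-tRNA synthetases had 9 of 35 higher and 4 lower and did not pass (adjusted p = 0.305). Proteasome subunits had 3 of 36 higher and 4 lower (adjusted p = 0.792), and ZNF zinc finger genes 98 of 428 higher and 86 lower (adjusted p = 0.766). Total-count scaling moved the median of all genes by -0.13 and those of these families by about as much, which does not test how a family stands against other genes; it brought the median of the initiation factors to 0.001.

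Integrins and tubulins stood below other genes in the same test. The integrin family was narrowed after its values had been seen, to leave out integrin-binding proteins. Integrins had 0 of 16 members higher and 8 lower, with ITGB8 at -0.63 ± 0.079 and ITGB4 at -0.52 ± 0.071 (adjusted p = 0.02, and adjusted p = 0.403 with an estimated correlation). Tubulins had 3 of 14 higher and 8 lower, with TUBB3 at -1.23 ± 0.188 (adjusted p = 0.045, and adjusted p = 0.4 with an estimated correlation). Their medians were -0.27 and -0.24. Other adhesion, cytoskeletal and matrix families did not pass: keratins had 8 of 20 higher and 5 lower (adjusted p = 0.118; median -0.026, mean 0.40), claudins 0 of 11 higher and 3 lower (adjusted p = 0.118), and collagens 7 of 30 higher and 4 lower (adjusted p = 0.726). Histone genes had 3 of 33 higher and 13 lower without passing as a set (adjusted p = 0.112). Among gene classes, 3035 of 13055 protein-coding genes were higher and 3161 lower, under a scaling that centres the bulk of genes, and 460 were higher and 241 lower by at least 2-fold. In the other classes 292 of 1866 long non-coding genes were higher and 147 lower, and 196 of 990 pseudogenes were higher and 64 lower.

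Small nucleolar and Cajal body RNAs formed the class with the clearest shift: 87 of 126 rose, 0 fell, and their median log2 fold change was 1.20. A bias in fragment size or length alone would raise other short RNAs as much. The median of this class exceeded that of 126 other short non-coding genes (0.65, 51 higher and 0 lower) by 0.55. The permutation p was 1e-05, the smallest the permutations can give. Among genes of 60 to 150 bases the excess was 0.77 (permutation p = 1e-04). These permutations treat genes as independent and do not measure spread between libraries. In washout replicates 1 to 3 the other short genes had medians of 0.42, 0.54 and 0.32, in the same order as this class. A bias in recovery that acts unequally on short RNAs is therefore not excluded. Transcription of the host gene could tie the change of each small RNA to that of its host. Over 118 pairs, which are not independent replicates, Spearman's rho was 0.03 (permutation p = 0.75). The host rose in 53 pairs and fell in 9, where the small RNAs had medians of 1.21 and 1.07. The pairs held 83 distinct hosts. Among all protein-coding genes 3035 of 13055 were higher and 3161 lower. A larger share of pairs thus had a host that rose, and a smaller share a host that fell. Host levels were exon counts, which do not measure transcription itself. No pair-by-pair tie between the changes of small RNA and host RNA was found. Hosts as a class rose more often than they fell, and host transcription stays open. One washout library alone did not carry the shift, since all 3 washout libraries (medians 0.74, 1.18 and 0.57) lay above the highest mock washout library (0.044). The part of the rise shared with other short RNAs stays open, because recovery of short RNA during extraction was not measured apart from the groups. A hypothesis for the rest is that these RNAs may be made or kept in greater amount together with the nucleolar genes that rose, such as DKC1, which was not tested here.

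Protein-coding genes that rose lay next to each other slightly more often than chance. The permutations in this paragraph treat genes as exchangeable and do not measure spread between samples. Gene length and GC content were not matched in them. Of 13032 neighbouring pairs 796 had both members higher, 1.13 times the mean of permutations within chromosomes (permutation p = 1e-05, the smallest they can give), and 1.12 times when expression level was matched (permutation p = 4e-05), which argues against chance order and against similar expression of neighbours. Reads running into a neighbour on the same strand cannot be told apart from regulation of neighbouring genes: pairs on opposite strands at least 10 kb apart had a ratio of 1.08 (permutation p = 0.131) against 1.14 for the other pairs, and the difference between these ratios was within chance (permutation p = 0.435). For genes that fell, pairs on opposite strands at least 10 kb apart had a ratio of 1.27 (permutation p = 6e-05) and the other pairs 1.03 (permutation p = 0.223), a difference beyond chance (permutation p = 0.00262) and opposite to what read-through on the same strand would give. Activation of Notch may act over neighbourhoods holding several genes, a biological explanation that was not tested.

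Rises of at least 2-fold outnumbered such falls 2.66 to 1. Among protein-coding genes the ratio was 1.91 (460 against 241; 95% binomial interval 1.63 to 2.24), and among genes at or above the median expression 4.10 (275 against 67; interval 3.13 to 5.44), which argues against non-coding features and low counts as the whole source. The intervals in this paragraph treat genes as independent draws and do not measure spread between samples. With the trend on gene length removed the ratio was 1.74 (674 against 388), with and without the replicate block. Library scaling stays open: with total-count scaling the ratio was 1.27 (638 against 504; interval 1.13 to 1.43), and no spike-in or cell number was used here to choose between scalings. Whether restored Notch activity raises total RNA per cell, a possible explanation, was therefore not tested.

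Of the 10 ways to split the 6 libraries into groups of 3, the real split called 7199 genes and the highest of the others 0. Only the real split itself called as many, and with 10 splits no share under 0.05 can be had. Each of the other splits mixed washout and mock washout libraries. The difference between conditions then adds to the spread within groups, so these splits do not show what chance alone would give.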
